A study of Homo sapiens with 9 samples.

How the data were processed

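RNA from 9 samples of MV4;11, an established human leukaemia line, was measured in 3 groups of 3 libraries (0.1% DMSO, 500 nM JQ1, 500 nM JQ1-PA), and each library was placed in its group by the treatment named in its label. Per the labels' protocols, cells were grown in RPMI-1640 medium with fetal calf serum, RNA was extracted with an RNeasy kit and polyadenylated RNA was made into libraries with the TruSeq RNA protocol, whose strand setting is not given in the sources used here. Per the submitters' processing notes, TopHat2, Bowtie2, HTSeq and edgeR were used with the genome build hg19. Their versions and settings are not given in the sources used here. The labels call the cells macrophages from peripheral blood.

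The authors deposited 1 table of CPM (read counts scaled to a common library size) for 15711 genes by Ensembl identifier. Every CPM value was a whole multiple of 1 step per library within 0.01 read, so whole reads were recovered for 100.0% of values. The library sizes behind the CPM were 18000549 to 22344034 reads, of which 15594804 to 19263949 (86.04 to 86.93%) fell in the listed genes. A count of 0 allows up to 3 reads, or 0.134 to 0.167 CPM, for counting error only. Identifiers were named from a gene name table (14264) and from GENCODE release 29 (963), and 484 stayed without a name. Of all, 10 identifiers share a symbol with another. That annotation is of GRCh38 and the deposited values of hg19, so no coordinates are given.

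The design, the gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1) with 1 coefficient per group, all 9 libraries in 1 fit, a variance trend and robust empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The 14801 genes with a mean CPM of at least 1 were tested, and 910 were left out. Equivalence of the compounds used 2 one-sided tests in the same limma fit with a margin of 1.5-fold. A response score per library averaged the signed distance from the DMSO mean over genes past the 3-group F test, and the compounds' scores were compared by an exact permutation test. Fold changes of both compounds share the DMSO libraries, so correlations, covariance and the share of equal signs were set beside 100 simulations of unchanged groups, and shared calls beside the overlap of independent lists. The slope between compounds allowed for error in both.

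The 23 gene lists, written from general knowledge of BET inhibitors and leukaemia, covered genes reported to rise or to fall under BET inhibitors, BET proteins and P-TEFb, MLL fusion targets, ribosome biogenesis, nucleotide metabolism, glycolysis, histones, monocyte and macrophage genes, NF-kB genes, interferon-stimulated genes, DNA replication, mitosis, apoptosis regulators, p53 targets, FLT3 signalling outputs, cholesterol synthesis, stress responses, lysosome and autophagy, ribosomal proteins, heat shock, housekeeping references and mitochondrially encoded transcripts. Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists. Another 6 lists held markers of B cells, T and NK cells, erythroid cells, megakaryocytes, granulocytes and stromal or epithelial cells. Lists share members, among them HEXIM1, BCL2, CDK6 and several histones. The named genes are 8 genes chosen in advance, the 8 largest rises and falls per compound with every treated library outside the DMSO range, up to 4 members per list with the largest change in JQ1, and the 5 largest differences each way between the compounds with no overlap of libraries; clone names were passed over. Genes with near-identical copies, such as histones, HSPA1A, HSPA1B and pseudogenes, share reads, and their values are uncertain. Results for some genes and markers are not reported here.

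Alternatives were pseudocounts of 0.25 and 4, no filter, a filter at a mean CPM of 5, median of ratios scaling, quantile normalization, only the groups compared, neither variance trend nor robust moderation, the replicate number as a block, each library left out in turn, equivalence margins of 1.25 and 2, a score on the BET lists alone, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Removal of 2 unnamed abundant gene models with rescaled CPM was chosen after seeing the data. On the recovered reads edgeR called 10656, 10567 and 421 genes for JQ1 against DMSO, JQ1-PA against DMSO and JQ1-PA against JQ1, and DESeq2 called 9820, 9597 and 170. Limma called 10111, 10333 and 223 of the edgeR genes the same way, and 9581, 9567 and 99 of the DESeq2 genes. Between the compounds limma called 367 genes, so many of its calls there were not shared. DESeq2 gave no adjusted p for 6890 genes in that comparison. The limma steps were tested on simulated data: of 100 genes changed by 0.5 on the log2 scale among 14801, 98, 97 and 96% were recovered in the 3 comparisons, with 10, 7 and 15 false calls among 14801 genes. Of 14601 unchanged genes 14585 were called equivalent between the compounds, as were 0 of 100 genes changed 2-fold. The changed genes all had a mean CPM above 5, so recovery and wrong calls of equivalence were not tested for lower genes. All simulated genes shared a single dispersion, and no simulated library stood apart as JQ1 replicate 3 did in the data. The number of false calls in the real fits was therefore not tested. Replicates of each group were compared by chi-square tests of their reads, and every pair differed by more than counting noise. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.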

Results

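MV4;11 is a human acute myeloid leukaemia line that carries an MLL-AF4 fusion and an internal tandem duplication in the receptor kinase FLT3. Its polyadenylated RNA was sequenced after culture with 0.1% DMSO (the vehicle), 500 nM JQ1 or 500 nM JQ1-PA, with 3 libraries per group and 9 in all. JQ1 binds the acetyl-lysine pocket of BET bromodomain proteins, among them BRD2 and BRD3. JQ1-PA is described here only by the name in the labels, under a series title that concerns click chemistry, and the length of treatment is not given in the sources used here. Between 15594804 and 19263949 reads fell in the listed genes of a library. A count of 0 allowed a level of up to 0.134 to 0.167 CPM (read counts scaled to a common library size), which covers counting error only. The labels do not say whether the replicates were separate cultures, so the p-values may measure technical spread alone.

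JQ1 against DMSO asks which transcripts BET inhibition changed in this line. MYC, the transcription factor that drives growth programmes in many leukaemias, fell from 444 ± 14.7 to 114 ± 2.87 CPM (mean ± SD, n = 3), 3.91-fold lower. The anti-apoptotic gene BCL2 fell from 182.5 ± 3.42 to 53.1 ± 1.01 CPM. CDK6, the cyclin-dependent kinase on which MLL-rearranged cells rely, fell from 505 ± 27.7 to 165 ± 7.84 CPM. HEXIM1, which holds the elongation kinase P-TEFb inactive, rose from 58.1 ± 0.78 to 239 ± 13.2 CPM. SERPINI1, which encodes the protease inhibitor neuroserpin, rose 15.7-fold, from 1.49 ± 0.241 to 23.4 ± 0.812 CPM. The log2 changes were -1.96 ± 0.04 for MYC, -1.76 ± 0.04 for BCL2, -1.61 ± 0.04 for CDK6, 2.02 ± 0.04 for HEXIM1 and 3.30 ± 0.08 for SERPINI1 (± SE, on the log2(CPM + 1) scale), with limma, Benjamini-Hochberg adjusted p of 5.18e-59 or less. Of the drug's targets, BRD2 rose from 261 ± 8.71 to 445 ± 20.8 CPM (limma adjusted p = 3.35e-38). BRD3 was called at 66.15 ± 0.811 against 70.9 ± 3.47 CPM (limma adjusted p = 0.0363). The call was lost without DMSO replicate 1 (0.0905), DMSO replicate 2 (0.0795), JQ1 replicate 1 (0.111) or JQ1 replicate 2 (0.182), and without the variance trend and robust moderation (0.105). Over all settings the adjusted p ran from 3.24e-05 to 0.182. In the deposited table these genes are ENSG00000136997 (MYC), ENSG00000171791 (BCL2), ENSG00000105810 (CDK6), ENSG00000186834 (HEXIM1), ENSG00000163536 (SERPINI1), ENSG00000204256 (BRD2) and ENSG00000169925 (BRD3).

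**Figure D1:**
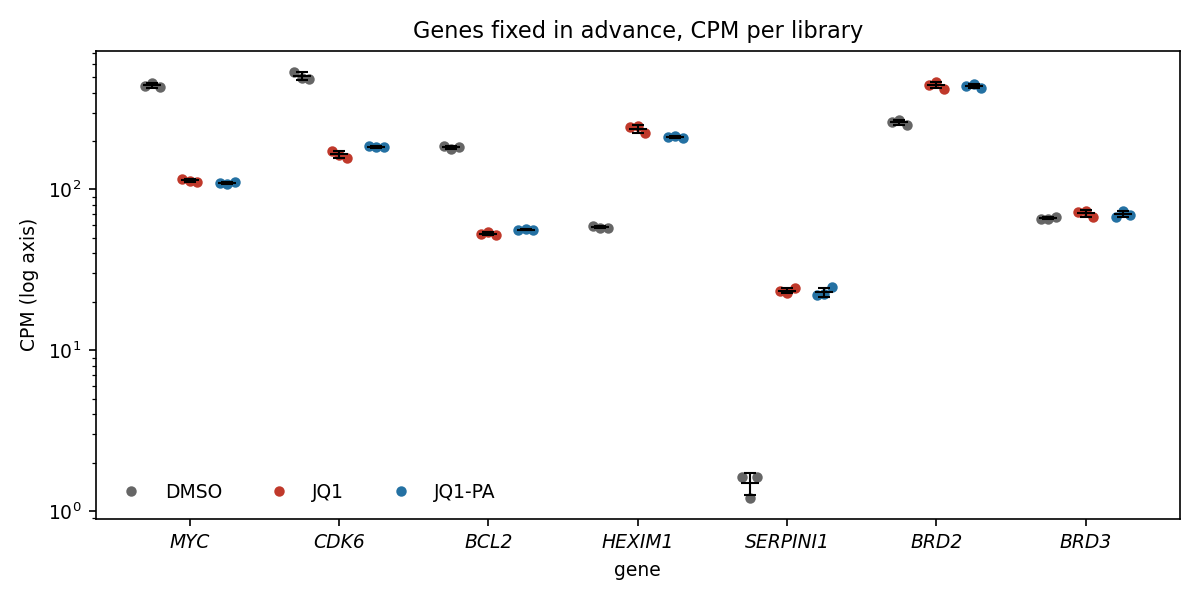
CPM of genes fixed in advance in each of the 9 libraries, on a log axis, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3). MYC, CDK6 and BCL2 lie lower and HEXIM1, SERPINI1 and BRD2 higher in both treated groups than in DMSO, while BRD3 lies at similar levels in the 3 groups.

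The steepest falls beyond the fixed genes were in CCR2, the receptor for the monocyte-attracting chemokine CCL2, which went from 82.7 ± 2.55 to 1.69 ± 0.0638 CPM (48.9-fold lower). Next was CSPG4, the proteoglycan NG2 that marks MLL-rearranged blasts, from 142 ± 0.829 to 5.12 ± 1.13 CPM (27.8-fold lower). B3GNT7, a glycosyltransferase of keratan sulfate synthesis, fell from 161 ± 3.92 to 7.68 ± 0.49 CPM. The galectin gene LGALS12, the adaptor gene HSH2D, the muscle protein gene MYBPH, INHBA (the activin A subunit) and the scaffold gene GRIP1 completed the 8 largest falls, with log2 changes of -3.65, -3.41, -3.31, -3.24 and -3.13. SAT1, the rate-limiting enzyme of polyamine catabolism, rose 14.2-fold, from 13.0 ± 1.04 to 184 ± 13.4 CPM. EFR3B, a plasma membrane anchor of phosphatidylinositol 4-kinase, stood at 0.222 ± 0.102 CPM in DMSO and 11.3 ± 0.872 CPM in JQ1. The histone gene H2AC6 rose from 2.97 ± 0.339 to 80.6 ± 4.74 CPM. H2BC11, FGD6 (a guanine nucleotide exchange factor), CAPN5 (a calpain protease) and MAP1A (a microtubule protein) rose by 3.13, 3.02, 2.99 and 2.81 on the log2 scale. Each of these genes lay outside the DMSO range in all 3 JQ1 libraries, with a limma adjusted p of 9.43e-43 or less.

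Among 9 tested genes reported to rise under BET inhibitors, all 9 rose with a median log2 change of 2.45 (9 passed when adjusted over the list alone). The list also shares HEXIM1 with the list of P-TEFb components. The linker and core histones, a list which shares H1-2, H2BC5, H2BC11, H2BC12 and H2BC21 with the first, rose in 13 of 13 members with a median of 1.95 (13 adjusted over the list alone). H2BC21 rose from 1.74 ± 0.326 to 17.2 ± 0.418 CPM and H2BC12 from 11.95 ± 0.522 to 74.4 ± 2.39 CPM. Histone genes exist in near-identical copies, so the split of reads among them is uncertain. Both lists stood apart from other genes in limma's camera test (Benjamini-Hochberg adjusted p = 2.62e-10 and 1.52e-10) and did so with an estimated correlation too (adjusted p = 0.00876 for each). Of 13 genes reported to fall, 12 fell (median -1.76, and 13 of 13 passed adjusted over the list alone). Among them were IL7R, the interleukin-7 receptor (17.04 ± 0.271 to 2.01 ± 0.31 CPM), TERT, the catalytic subunit of telomerase (17.1 ± 1.52 to 2.37 ± 0.213 CPM), and the Toll-like receptor homologue CD180 (96.2 ± 2.57 to 19.9 ± 1.04 CPM). The exception was IL10RA, the interleukin-10 receptor, with a log2 change of 1.16. It and the other exceptions to a list's main direction were chosen after their values were seen. The camera call of this list (adjusted p = 1.08e-07) was lost with an estimated correlation (adjusted p = 0.068 with an estimated correlation). In the list of BET proteins and P-TEFb components, 11 of 17 members rose, led by the elongation factor ELL2 (8.83 ± 0.509 to 40.6 ± 3.24 CPM), HEXIM1 and AFF4, a scaffold of the super elongation complex (48.7 ± 1.89 to 86.8 ± 4.15 CPM). LARP7 (-0.24) and AFF1 (-0.15) fell and 4 did not pass (13 adjusted over the list alone). Its camera adjusted p was 0.00298 (adjusted p = 0.449 with an estimated correlation).

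Genes of ribosome production, many of them MYC targets, fell in 25 of 25 members (median log2 change -0.99; 25 adjusted over the list alone). NOP16 fell from 52.9 ± 2.95 to 16.9 ± 0.78 CPM, UTP20 from 91.2 ± 1.77 to 32.1 ± 0.747 CPM and RRS1 from 72.4 ± 4.27 to 25.9 ± 1.24 CPM, each needed for nucleolar processing or assembly of pre-ribosomes. The camera adjusted p was 5.66e-14 (adjusted p = 0.136 with an estimated correlation). In nucleotide and one-carbon metabolism 14 of 20 members fell, 5 rose and 1 did not pass (median -0.59; 19 adjusted over the list alone). The purine enzyme PFAS fell from 160 ± 2.14 to 48.5 ± 2.14 CPM, spermidine synthase SRM from 166 ± 2.17 to 55.3 ± 3.12 CPM and CAD, which starts pyrimidine synthesis, from 303 ± 2.96 to 131 ± 4.48 CPM. In contrast, MTHFD2, TYMS, PPAT, SHMT1 and IMPDH2 rose by 0.11 to 0.50 on the log2 scale (camera adjusted p = 0.000224; adjusted p = 0.449 with an estimated correlation). Heat shock genes fell in 16 of 18 members (median -0.69; 17 adjusted over the list alone). Among them were the HSP90 co-chaperone FKBP4 (242 ± 7.37 to 82.3 ± 2.66 CPM) and the mitochondrial chaperonin HSPE1 (36.6 ± 0.615 to 14.4 ± 0.919 CPM). BAG3 was higher (0.16) and DNAJB1 did not pass. HSPA1A and HSPA1B also fell, but their near-identical sequences leave the level of each uncertain. The camera adjusted p was 1.08e-07 (adjusted p = 0.258 with an estimated correlation). Glycolysis split, with 11 members lower, 5 higher and 4 not passing (median -0.21; 16 adjusted over the list alone; camera adjusted p = 0.215). HK2, the hexokinase bound to mitochondria, fell from 113 ± 2.42 to 40.1 ± 2.12 CPM and LDHA, which makes lactate, from 842 ± 12.8 to 526 ± 11.2 CPM. ENO2 rose from 3.20 ± 0.586 to 9.23 ± 0.439 CPM.

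Genes of mitosis and G2/M rose in 19 of 24 members, while UBE2C (-0.32), BUB1B (-0.19), AURKA (-0.10) and TOP2A (-0.10) fell and PLK1 did not pass (median 0.22; 23 adjusted over the list alone). CENPE, a kinetochore motor, rose from 102 ± 0.523 to 158 ± 1.88 CPM, NUSAP1, a spindle protein, from 168 ± 4.96 to 259 ± 9.71 CPM and the spindle motor KIF11 from 123 ± 2.89 to 189 ± 7.26 CPM (camera adjusted p = 0.000282; adjusted p = 0.438 with an estimated correlation). DNA replication and G1/S genes went both ways, 14 higher, 10 lower and 1 not passing (median 0.14; 24 adjusted over the list alone; camera adjusted p = 0.263). CCNE2 (cyclin E2) rose from 15.2 ± 0.751 to 31.8 ± 1.12 CPM and RRM2, a ribonucleotide reductase subunit, from 272 ± 0.877 to 490 ± 13.6 CPM. CDK4 fell from 107 ± 2.09 to 53.5 ± 1.97 CPM and the replicative helicase gene MCM2 from 332 ± 2.15 to 198 ± 11.5 CPM. Lysosome and autophagy genes rose in 16 of 22 members, with OPTN, TFEB, ATG7 and CTSD lower and 2 not passing (median 0.30; 20 adjusted over the list alone). The sialidase NEU1 rose from 29.5 ± 0.994 to 108 ± 5.31 CPM, the phagophore lipid-transfer protein gene ATG2A from 37.35 ± 0.665 to 97.4 ± 6.95 CPM and MAP1LC3B, which marks autophagosomes, from 24.8 ± 0.796 to 60.5 ± 2.22 CPM (camera adjusted p = 9.42e-05; adjusted p = 0.438 with an estimated correlation).

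Monocyte and macrophage genes fell in 12 of 18 members, with CEBPB, KLF4, ITGAM, CTSB and CD86 higher and ITGAX not passing (median -0.46; 17 adjusted over the list alone). CSF1R, the receptor for macrophage colony-stimulating factor, fell from 31.7 ± 1.59 to 4.12 ± 0.271 CPM, the scavenger receptor CD36 from 18.7 ± 2.33 to 3.61 ± 0.406 CPM and the myeloid transcription factor SPI1 from 180 ± 6.32 to 48.3 ± 3.23 CPM (camera adjusted p = 0.0183; adjusted p = 0.438 with an estimated correlation). Granulocyte markers moved with them, since 6 of 6 tested fell, including the azurophil protease genes PRTN3 (1100 to 478 CPM), ELANE (440 to 256 CPM) and CTSG (234 to 134 CPM). MLL fusion targets were mixed, with 10 of 20 lower, 6 higher and 4 not passing (median -0.19; 17 adjusted over the list alone; camera adjusted p = 0.179). BCL2, CDK6, TCF4 (29.5 ± 0.787 to 11.9 ± 0.0857 CPM) and the SUMO protease SENP6 (74.6 ± 1.51 to 37.1 ± 1.77 CPM) led the falls. HOXA9 (0.88) and HOXA10 (0.70), the homeobox genes of the fusion programme, rose. Apoptosis regulators split into 11 lower, 8 higher and 2 not passing (19 adjusted over the list alone). Beside BCL2, the BH3-only gene BIK fell (9.24 ± 0.485 to 4.18 ± 0.0515 CPM). The BH3-only gene BCL2L11 (32.8 ± 0.721 to 59.6 ± 0.286 CPM) and CASP9, the initiator caspase of the mitochondrial pathway (11.7 ± 0.786 to 25.4 ± 1.51 CPM), rose. The median (-0.12) and mean (-0.08) of this list were negative where camera pointed up, and it was not called (adjusted p = 0.873).

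Of 18 p53 targets, 11 rose, 2 did not pass, and AEN, PHLDA3, BAX, TNFRSF10B and MDM2 fell (median 0.41; 16 adjusted over the list alone). The stress-response gene SESN2 rose from 5.70 ± 0.592 to 24.7 ± 2.3 CPM, TP53INP1 from 2.86 ± 0.462 to 13.5 ± 0.488 CPM and the growth arrest gene GADD45A from 4.07 ± 0.927 to 11.3 ± 1.05 CPM (camera adjusted p = 0.0237; adjusted p = 0.46 with an estimated correlation). Outputs of FLT3 signalling through STAT5 and ERK were higher in 9 of 16 members, lower in 5 (FOSL1, ETV4, SPRY2, BCL6 and CISH) and not called in 2 (median 0.28; 15 adjusted over the list alone). ETV5 rose from 8.92 ± 0.92 to 36.1 ± 4.92 CPM, the ERK phosphatase DUSP5 from 1.06 ± 0.297 to 4.07 ± 0.249 CPM. FOSL1 fell from 13.0 ± 0.858 to 3.57 ± 0.516 CPM. The list was not called (camera adjusted p = 0.0641). It passed without DMSO replicate 3 (adjusted p = 0.0499) and with no filter on low values (0.0377), reaching at most 0.117 in other settings. Among 19 genes of the integrated stress and unfolded protein responses, 11 fell, 5 rose (SESN2, ATF3, DDIT4, ASNS and PHGDH) and 3 did not pass (median -0.36; 17 adjusted over the list alone; camera adjusted p = 0.217). The endoplasmic reticulum chaperone HSPA5 fell from 674 ± 13.9 to 369 ± 14.9 CPM. The transcription factor ATF3 rose from 1.16 ± 0.331 to 7.12 ± 1.02 CPM. Cholesterol synthesis genes were lower in 11 of 21 members, higher in MVD, SC5D, IDI1 and LSS and not called in 6 (median -0.17; 15 adjusted over the list alone; camera adjusted p = 0.327). MSMO1 stood at 17.03 ± 1.49 and 8.12 ± 0.45 CPM.

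NF-kB and inflammatory genes changed in 7 of 12 members, 5 up and 2 down (TNFAIP3 and NFKBIE), with a median of 0.09 (7 adjusted over the list alone; camera adjusted p = 0.327). NFKBIZ, a nuclear IkB protein, rose from 2.66 ± 0.2 to 8.98 ± 0.299 CPM. TNFAIP3, which restrains NF-kB, fell from 17.8 ± 0.742 to 9.88 ± 0.442 CPM. Of 15 interferon-stimulated genes, IRF7 (15.5 ± 0.825 to 74.0 ± 4.05 CPM), IFI6, STAT2, RSAD2 and IRF9 rose. XAF1 (59.6 ± 0.901 to 11.2 ± 0.347 CPM), USP18, IFIH1 and OAS2 fell and 6 did not pass (9 adjusted over the list alone; camera adjusted p = 0.327). Their median was 0.0138, and turned negative without DMSO replicate 1 (-0.00417) and at a mean CPM of at least 5 (-0.00243). Ribosomal proteins changed little: 9 of 28 were higher, RPL6 was lower and 18 did not pass (median 0.05; 9 adjusted over the list alone; camera adjusted p = 0.217). The list passed without JQ1 replicate 3 (0.0223) and after median of ratios scaling (0.0234) and with the 2 unnamed gene models removed (0.0252), and reached at most 0.318. RPLP0 stood at 1434 ± 22.3 and 1668 ± 79 CPM. Housekeeping references split into 7 higher, 5 lower and 2 not passing (13 adjusted over the list alone; camera adjusted p = 0.645). The transferrin receptor TFRC fell from 772 ± 0.676 to 423 ± 7.65 CPM and B2M rose from 532 ± 8.68 to 675 ± 15.3 CPM. The list's median was 0.0712 and its mean -0.0208. Mitochondrially encoded transcripts, a sign of RNA quality, made up 4.13 to 4.31% of the DMSO libraries and 4.51 to 4.7% of the JQ1 libraries. They were higher in 7 of 13 members and lower in 0 (median 0.0774 and, after quantile normalization, -0.0832, with 7 adjusted over the list alone and a camera adjusted p of 0.299). MT-CO3 turned to -0.343 and MT-CO1 to -0.209 under that normalization.

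**Figure D2:**
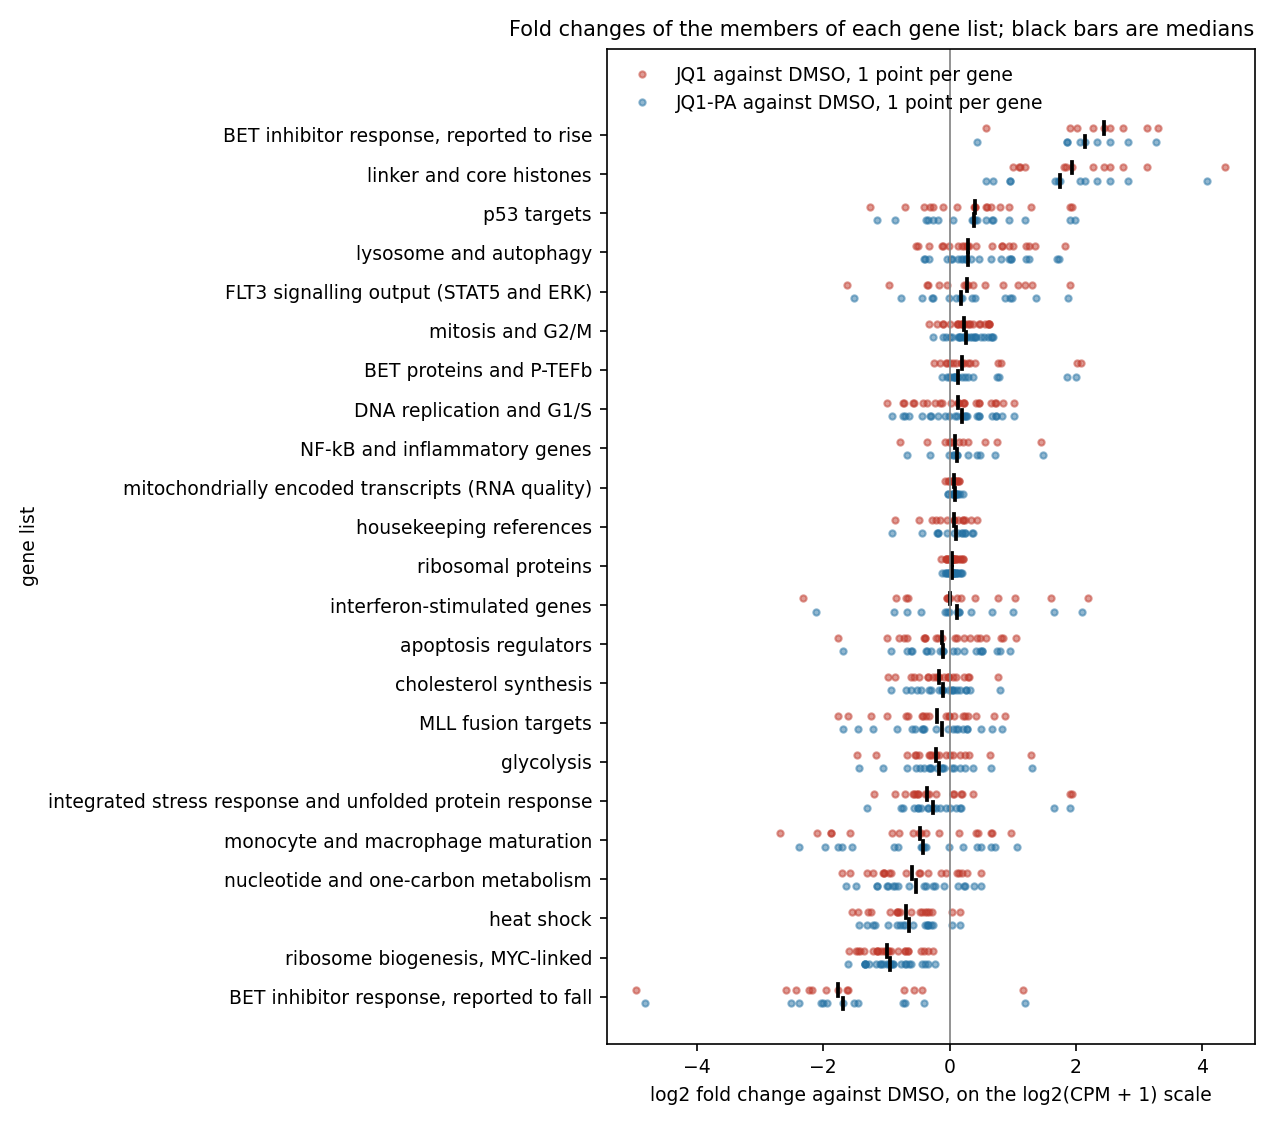
Log2 fold changes against DMSO of the tested members of the 23 gene lists, with 1 point per gene for JQ1 and for JQ1-PA and a black bar at each list's median. The list of genes reported to rise lies at a median of 2.45 for JQ1 and 2.15 for JQ1-PA, and ribosome biogenesis at -0.988 and -0.945; the mitochondrial medians turn negative for JQ1 and reach 0 for JQ1-PA after quantile normalization.

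Across all 14801 genes tested by limma, 4788 were higher and 5716 lower in JQ1 than in DMSO at an adjusted p under 0.05, which is 71.0% of them. At least 2-fold changes were seen in 443 of the higher and 882 of the lower genes. The balance of all calls moved with the scaling. It was 5317 higher and 5363 lower after median of ratios scaling, and 5676 and 5036 after quantile normalization. On the recovered reads edgeR gave 5332 and 5324, and DESeq2 4857 and 4963. Over all tested genes the libraries of the groups did not overlap in 10529 (71.1%), against 10% by chance. Camera called 11 of the 23 lists, 6 up and 5 down, of which the list reported to rise and the histones were also called with an estimated correlation. JQ1 replicate 3 stood apart from its group: 2 gene models without a name took 7.56% of it against 2.3 to 3.1% of the other libraries. Its reads differed from those of the other JQ1 libraries by a chi-square of 35.8 and 39.5 per degree of freedom, where other replicate pairs gave 1.37 to 2.73. Without it, limma called 4943 genes higher and 5349 lower.

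JQ1-PA was compared with DMSO in the same way and at the same dose as JQ1. MYC fell from 444 ± 14.7 to 110 ± 1.73 CPM (n = 3), BCL2 from 182.5 ± 3.42 to 56.25 ± 0.694 CPM and CDK6 from 505 ± 27.7 to 184 ± 2.09 CPM. HEXIM1 rose from 58.1 ± 0.78 to 212.5 ± 3.23 CPM, SERPINI1 from 1.49 ± 0.241 to 22.95 ± 1.49 CPM and BRD2 from 261 ± 8.71 to 439 ± 12.4 CPM. In log2 terms the changes were -2.004 ± 0.04 for MYC, -1.68 ± 0.04 for BCL2, -1.45 ± 0.04 for CDK6, 1.85 ± 0.04 for HEXIM1, 3.27 ± 0.08 for SERPINI1 and 0.75 ± 0.03 for BRD2 (± SE), with limma adjusted p of 2.36e-37 or less. BRD3 (70.1 ± 2.78 CPM) did not pass in limma (adjusted p = 0.0777). It passed in 7 of 21 settings: without JQ1 replicate 3 (0.0383) or JQ1-PA replicate 1 (0.0424), after median of ratios scaling (0.0406), after quantile normalization (0.00306), with only the 2 groups compared (0.0424), with the 2 unnamed gene models removed (0.03) and with edgeR (0.0225). The adjusted p reached at most 0.352. The 8 largest falls held CCR2 (to 1.97 ± 0.447 CPM), CSPG4 (to 5.51 ± 0.208 CPM), B3GNT7 (to 8.88 ± 0.0629 CPM), LGALS12, HSH2D, INHBA, MYBPH and TGM5. TGM5, a transglutaminase gene, fell from 52.1 ± 2.12 to 5.24 ± 0.875 CPM. The 8 largest rises held H2AC6 (to 65.6 ± 4.4 CPM), SAT1 (to 165 ± 3.18 CPM), EFR3B (to 11.9 ± 0.815 CPM), SERPINI1, FGD6, CAPN5, MAP1A and CEMIP2. CEMIP2, a cell-surface hyaluronidase gene, rose from 5.60 ± 0.831 to 45.4 ± 0.813 CPM.

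The list reported to rise under BET inhibitors was higher in 9 of 9 members (median 2.15; 9 adjusted over the list alone) and the histones in 13 of 13 (median 1.75; 13 adjusted over the list alone), with camera adjusted p of 3.21e-09 and 4.73e-09 and, with an estimated correlation, adjusted p = 0.0138 and 0.014. In the list reported to fall, 12 of 13 members fell, IL10RA (1.195) again being the exception (median -1.68; 13 adjusted over the list alone; camera adjusted p = 2.78e-08, and adjusted p = 0.055 with an estimated correlation). Ribosome biogenesis fell in 25 of 25 members, with NOP16 at 16.8 ± 0.224 CPM (median -0.945; 25 adjusted over the list alone; camera adjusted p = 4.13e-15, and adjusted p = 0.117 with an estimated correlation). Nucleotide metabolism fell in 15 of 20 members and rose in MTHFD2, TYMS, PPAT, SHMT1 and IMPDH2, with PFAS at 50.95 ± 2.48 CPM (median -0.52; 20 adjusted over the list alone; camera adjusted p = 0.000151, and adjusted p = 0.517 with an estimated correlation). Heat shock genes fell in 16 of 18 members, with FKBP4 at 88.7 ± 4.41 CPM, BAG3 higher (0.17) and DNAJB1 not passing (median -0.64; 17 adjusted over the list alone; camera adjusted p = 3.84e-08, and adjusted p = 0.239 with an estimated correlation). Mitosis genes rose in 19 of 24, with CENPE at 165.5 ± 6.15 CPM, UBE2C and BUB1B lower and AURKA, PLK1 and TOP2A not passing (median 0.26; 21 adjusted over the list alone; camera adjusted p = 0.000142, and adjusted p = 0.423 with an estimated correlation). Lysosome and autophagy genes rose in 16 of 22, with NEU1 at 100.5 ± 4.5 CPM and OPTN, TFEB and ATG7 lower (median 0.30; 19 adjusted over the list alone; camera adjusted p = 7.54e-05, and adjusted p = 0.423 with an estimated correlation). Monocyte genes fell in 11 of 18, with CSF1R at 5.30 ± 0.527 CPM and CEBPB, KLF4, CTSB, ITGAM and CD86 higher (median -0.42; 17 adjusted over the list alone; camera adjusted p = 0.0164, and adjusted p = 0.424 with an estimated correlation), and all 6 tested granulocyte markers fell beside them, PRTN3 to 463 CPM. The BET and P-TEFb list was higher in 9 of 17, with ELL2 at 38.3 ± 3.14 CPM and AFF1 lower (median 0.14; 10 adjusted over the list alone; camera adjusted p = 0.00391, and adjusted p = 0.517 with an estimated correlation).

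The remaining lists were not called for JQ1-PA. MLL fusion targets split into 8 higher and 10 lower, with TCF4 at 12.1 ± 0.387 CPM (18 adjusted over the list alone; camera adjusted p = 0.195). The p53 targets split into 11 higher and 5 lower, with TP53INP1 at 14.15 ± 0.567 CPM (16 adjusted over the list alone; 0.0801), and FLT3 outputs into 9 higher and 5 lower, with ETV5 at 35.3 ± 2.11 CPM (14 adjusted over the list alone; 0.178). Glycolysis was higher in 5 and lower in 12 members, with HK2 at 41.0 ± 0.516 CPM (18 adjusted over the list alone; camera adjusted p = 0.178). DNA replication was higher in 13 and lower in 9, with CCNE2 at 31.95 ± 0.865 CPM (24 adjusted over the list alone; 0.195). Stress responses were higher in PHGDH, ASNS, ATF3 and SESN2 and lower in 12 (16 adjusted over the list alone; 0.144). Cholesterol synthesis was higher in 6 and lower in 11 members (17 adjusted over the list alone; camera adjusted p = 0.445). NF-kB genes were higher in 5 and lower in TNFAIP3 and NFKBIE (7 adjusted over the list alone; 0.306), and interferon-stimulated genes higher in 6 and lower in XAF1, USP18, IFIH1 and OAS2 (10 adjusted over the list alone; 0.416). Apoptosis regulators were higher in 9 and lower in 9, with BCL2L11 at 57.7 ± 0.398 CPM (18 adjusted over the list alone; camera adjusted p = 0.927, pointing up where the median was -0.106 and the mean -0.0481). Ribosomal proteins were higher in 8 of 28 and lower in RPL6 (8 adjusted over the list alone; camera adjusted p = 0.365). Housekeeping references were higher in 7 and lower in 5 with a median of 0.0977 and a mean of -0.00887 (13 adjusted over the list alone; 0.69). Mitochondrial transcripts were higher in 7 of 13 with a median of 0.0837 that became 0 after quantile normalization (7 adjusted over the list alone; 0.274). Mitochondrial transcripts made up 4.53 to 4.79% of the JQ1-PA libraries.

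Limma called 5175 genes higher and 5207 lower in JQ1-PA than in DMSO, 70.1% of those tested, with 441 higher and 753 lower by at least 2-fold. All calls numbered 5278 higher and 5271 lower after median of ratios scaling, and 5649 and 4947 after quantile normalization. Over all tested genes the groups' libraries did not overlap in 10743 (72.6%), against 10% by chance. Camera called 10 lists, 5 up and 5 down, and those reported to rise and the histones were also called with an estimated correlation.

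JQ1-PA against JQ1, at 500 nM each, asks where the compounds differed. OSGIN1, an oxidative stress response gene, was 2.79-fold higher in JQ1-PA (10.1 ± 1.11 CPM) than in JQ1 (3.63 ± 0.4 CPM) and lowest in DMSO (0.796 ± 0.275 CPM). NQO1, a quinone reductase, stood at 27.7 ± 0.339 CPM in DMSO, fell to 22.8 ± 0.89 CPM in JQ1 and rose to 48.1 ± 3.48 CPM in JQ1-PA, 2.11-fold above JQ1. GCLM, a subunit of the enzyme that limits glutathione synthesis, stood at 35.4 ± 1.8, 49.6 ± 3.55 and 86.2 ± 3.57 CPM in DMSO, JQ1 and JQ1-PA. HMOX1 (haem oxygenase, which breaks haem down) stood at 2.10 ± 0.229, 3.94 ± 0.514 and 7.24 ± 0.625 CPM. SLC48A1, a haem transporter, was 1.58-fold higher in JQ1-PA (44.3 ± 0.651 CPM) than in JQ1 (28.1 ± 1.7 CPM), whose level lay beside that of DMSO (28.8 ± 3.08 CPM). These 5 largest rises had log2 differences of 1.26 ± 0.12, 1.04 ± 0.05, 0.79 ± 0.05, 0.74 ± 0.11 and 0.64 ± 0.06 (± SE), with 95% intervals of 1.04 to 1.49, 0.93 to 1.15, 0.69 to 0.88, 0.52 to 0.96 and 0.53 to 0.75. Their limma adjusted p was 7.23e-07 or less and stayed at or under 0.0211 under every alternative that gave one. OSGIN1 and HMOX1 have none at a mean CPM of at least 5 or with DESeq2. They are ENSG00000140961, ENSG00000181019, ENSG00000023909, ENSG00000100292 and ENSG00000211584 in the deposited table.

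**Figure D3:**
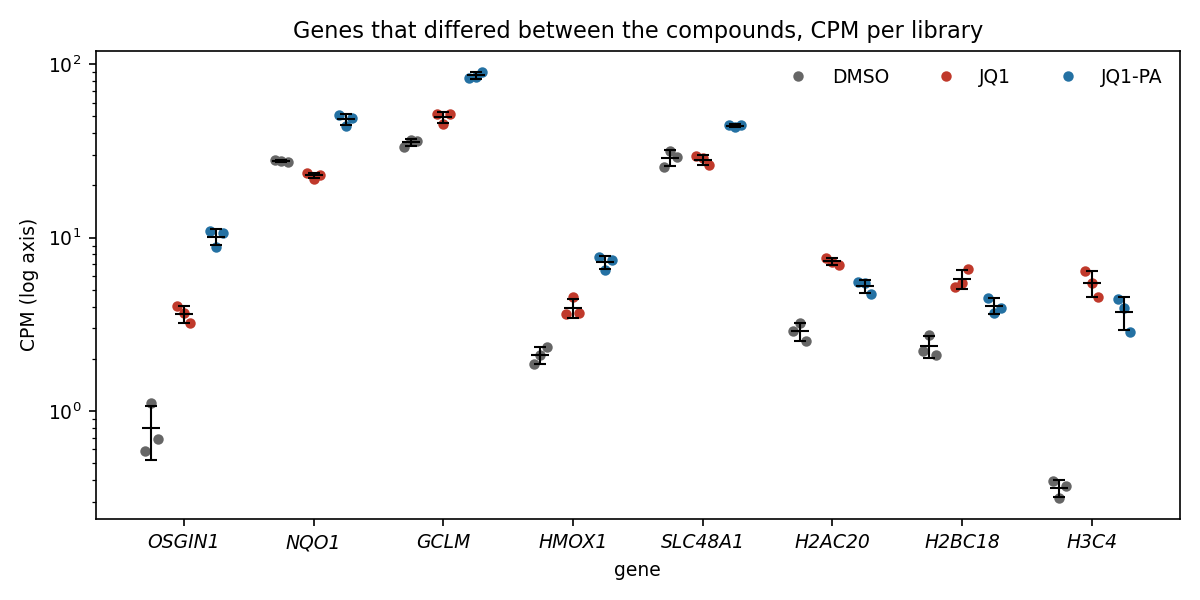
CPM per library of 8 genes that differed between the compounds, on a log axis, with bars at the group mean and error bars of 1 SD (n = 3). OSGIN1, NQO1, GCLM, HMOX1 and SLC48A1 lie highest in JQ1-PA, whereas the histone genes H2AC20, H2BC18 and H3C4 lie between their DMSO and JQ1 levels.

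The largest differences in the other direction were in the histone genes H3C15 (2.80 ± 0.521 CPM in JQ1 and 1.61 ± 0.602 CPM in JQ1-PA), H3C4 (5.46 ± 0.93 and 3.75 ± 0.809 CPM), H2BC18 (5.75 ± 0.725 and 4.03 ± 0.425 CPM) and H2AC20 (7.29 ± 0.312 and 5.26 ± 0.44 CPM). HNRNPA1P25 lay among them, a pseudogene whose reads cannot be cleanly parted from its parent's (1.49 ± 0.247 and 0.798 ± 0.0885 CPM). Their limma adjusted p lay between 0.00968 and 0.0318, and each call hung on single libraries. Without the variance trend and robust moderation all 5 were lost (0.194, 0.22, 0.152, 0.0809 and 0.0626), H3C4 was also lost with a pseudocount of 0.25 (0.0769) and HNRNPA1P25 with a pseudocount of 4 (0.0507). Without JQ1 replicate 1 it was lost for H3C4 (0.189) and H2AC20 (0.0636), without JQ1 replicate 2 for H3C4 (0.0734) and HNRNPA1P25 (0.131). Without JQ1 replicate 3 it was lost for H3C15 (0.119), H2BC18 (0.15) and HNRNPA1P25 (0.0951), without JQ1-PA replicate 1 for HNRNPA1P25 (0.0971). Without JQ1-PA replicate 2 it was lost for H3C15 (0.212), H3C4 (0.0585), H2BC18 (0.138) and HNRNPA1P25 (0.0637), and without JQ1-PA replicate 3 for H3C4 (0.345), H2BC18 (0.0967), H2AC20 (0.145) and HNRNPA1P25 (0.126). The identifiers are ENSG00000203852, ENSG00000197409, ENSG00000203814, ENSG00000184260 and ENSG00000231206 in that order. As a list the histones were lower in JQ1-PA than in JQ1 by a median of -0.21, with 5 of 13 members lower and 8 not passing (7 adjusted over the list alone). The list reported to rise under BET inhibitors differed by -0.19, with H2BC12, H1-2 and HEXIM1 lower and 6 not passing (7 adjusted over the list alone). Camera called both (adjusted p = 5.12e-17 and 4.17e-12), also with an estimated correlation (adjusted p = 0.0032 for each).

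Among the fixed genes, CDK6 was higher in JQ1-PA than in JQ1 by 0.16 ± 0.04 on the log2 scale (SE; limma adjusted p = 0.00386; 95% interval 0.09 to 0.23), and HEXIM1 differed by -0.17 ± 0.04 (limma adjusted p = 0.00335; -0.24 to -0.09). HEXIM1 lost its call without JQ1 replicate 2 (0.057), without JQ1-PA replicate 3 (0.0576) and without the variance trend and robust moderation (0.208). CDK6 lost it without the variance trend and robust moderation (0.255) and with DESeq2 (0.0601). No difference was called for MYC (-0.05, 95% interval -0.116 to 0.025), BCL2 (0.08, 0.002 to 0.161 before adjustment), SERPINI1 (-0.03, -0.19 to 0.13), BRD2 (-0.02, -0.09 to 0.05) or BRD3 (-0.01, -0.10 to 0.07). The sign turned for BRD2 without JQ1 replicate 2 (0.0125) or JQ1-PA replicate 3 (0.00381) and for BRD3 without JQ1 replicate 2 (0.0116) or JQ1-PA replicate 1 (0.00985). GABARAPL1, an autophagosome protein gene, was higher in JQ1-PA by 0.49, CD180 by 0.28 and the pre-ribosome gene UTP20 by 0.21, and H2AC6 differed by -0.29 (limma adjusted p of 0.0015, 0.000183, 0.00265 and 0.000805). All 4 calls were lost without the variance trend and robust moderation (0.118, 0.0546, 0.0937 and 0.169), and that of UTP20 also with DESeq2 (0.0754).

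Camera also called nucleotide metabolism up between the compounds (median 0.0681, 0 of 20 members passing, 3 adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.883 with an estimated correlation). It lost the call without JQ1 replicate 3 (0.291), JQ1-PA replicate 1 (0.077) or JQ1-PA replicate 3 (0.0836). It also lost it after median of ratios scaling (0.226), after quantile normalization (0.0696), at a mean CPM of at least 5 (0.0991), with only the 2 groups compared (0.0545) and with the 2 gene models removed (0.105). It called p53 targets down (-0.0337, 0 of 18, 1 adjusted over the list alone; adjusted p = 0.00767, and adjusted p = 0.823 with an estimated correlation). FLT3 outputs were called down too (-0.0333, 0 of 16, 0 adjusted over the list alone; adjusted p = 0.00767, and adjusted p = 0.465 with an estimated correlation), but not without JQ1-PA replicate 3 (0.0836). Ribosomal proteins were called down (-0.00491, 0 of 28, 0 adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.883 with an estimated correlation), but not without JQ1-PA replicate 2 (0.142) or JQ1-PA replicate 3 (0.0836) or after quantile normalization (0.552). Without JQ1 replicate 1 or JQ1 replicate 2 the call was lost too (0.202 and 0.209) and the median turned positive (0.00924 and 0.0164). In each of these 4 lists limma, adjusted over all genes, passed 0 members, beside 2246 genes at an unadjusted p under 0.05 in the whole table. The other 17 lists were not called, at adjusted p of 0.0519 or more. The BET and P-TEFb list, at 0.0519, passed without JQ1 replicate 3 (0.00482), DMSO replicate 1 (0.0497) or DMSO replicate 2 (0.0487) and turned in sign without JQ1 replicate 1 (0.00271). It also passed at a mean CPM of at least 5 (0.0196), after median of ratios scaling (0.0015), after quantile normalization (0.00915), with the 2 gene models removed (0.00485) and with the replicate block (0.0495), in a range of 0.0015 to 0.277. MLL fusion targets (0.0499), DNA replication (0.0332) and heat shock (0.0288) passed without JQ1 replicate 1, and stress responses (0.0317) without JQ1 replicate 3. Heat shock (0.028) and mitochondrial transcripts (0.00262) passed after quantile normalization, and housekeeping references passed after median of ratios scaling with a turned median of -0.0323 (0.0395). The members that passed in these lists outside the genes above were LARP7 (0.21), PBX3 (0.14), CTSS (0.18), MCM5 (0.155) and VLDLR (0.24), chosen after their values were seen, and SENP6, SPI1 and CSF1R, all higher in JQ1-PA. SPI1 lost its call without JQ1 replicate 2 (0.107) or JQ1-PA replicate 3 (0.0652), without the variance trend and robust moderation (0.221), with edgeR (0.0564) and with DESeq2 (0.163). CSF1R lost it without DMSO replicate 3 (0.0563), JQ1 replicate 1 (0.083), JQ1 replicate 3 (0.099) or JQ1-PA replicate 2 (0.244). It also lost it with a pseudocount of 4 (0.0768), after median of ratios scaling (0.0699), after quantile normalization (0.0811), with only the 2 groups compared (0.119), without the variance trend and robust moderation (0.15), with the 2 gene models removed (0.0515) and with edgeR (0.122). SENP6 lost it without any single library but JQ1 replicate 2 (0.0568 to 0.152), and in 17 of 21 settings in all, up to 0.366 with DESeq2. The median differed in sign from camera for glycolysis, apoptosis regulators, lysosome and autophagy, housekeeping references and mitochondrial transcripts, and the mean did for interferon-stimulated genes.

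Limma called 325 genes higher and 42 lower in JQ1-PA than in JQ1, 2.48% of those tested, with 2 differing by at least 2-fold and 2246 at an unadjusted p under 0.05. The median absolute log2 difference of the calls was 0.199. Over all tested genes the libraries of the compounds did not overlap in 2764 (18.7%), against 10% by chance. The split of the calls moved with the scaling, where the median of ratios centres the differences: 88.6% were higher in CPM as deposited, 48.4% after median of ratios scaling (163 higher, 174 lower), 58.6% after quantile normalization (197 and 139) and 67.3% once the 2 unnamed gene models were removed (247 and 120). Among calls on the recovered reads 43.0% were higher with edgeR and 41.2% with DESeq2. The split also hung in part on JQ1 replicate 3, without which 66.6% were higher (245 higher, 123 lower). Without the other libraries the share stayed at 86.3% to 93.5%, while the number of calls moved: 22 were lower without JQ1 replicate 1 and 26 without JQ1 replicate 2. There were 173 higher and 18 lower without JQ1-PA replicate 2, and 130 higher and 12 lower without JQ1-PA replicate 3. Camera called 6 lists, and 3 without JQ1-PA replicate 3.

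A missed threshold does not show that the compounds acted alike, so equivalence was tested on its own. The levels under JQ1-PA and JQ1 were equivalent within 1.5-fold in 14734 of 14801 genes (99.5%) and within the narrowest margin tried in 12484 (84.3%), with a median 95% interval of ± 0.131 on the log2 scale. The margins were applied on the log2(CPM + 1) scale, where low genes pass more easily. With a pseudocount of 0.25 the number equivalent within 1.5-fold was 14156. Of the 10732 genes that differed among the 3 groups, 10684 were equivalent within 1.5-fold. Of the 1325 genes changed at least 2-fold by JQ1, 1322 were called the same way for JQ1-PA, 1127 of them also at least 2-fold, and 90 differed between the compounds. The opposite calls were NQO1 and TALDO1, a pentose phosphate pathway gene chosen after its values were seen (-0.12 with JQ1 and 0.14 with JQ1-PA; limma adjusted p = 8.28e-08 between them). Called in common were 4561 higher and 5027 lower genes, against 1674 and 2011 for independent lists. Across genes, which are not independent replicates, the fold changes correlated at r = 0.985 and rho = 0.975, where unchanged groups simulated against the same DMSO libraries gave 0.502 and 0.462. The covariance was 0.349 against 0.00396 simulated, a difference of 0.345, and 92.6% of genes had the same sign (66.7% simulated). Independent lists leave out the shared DMSO libraries, which cannot be split into parts of 2 or more, so part of the excess of shared calls over them may come from the shared controls. The slope of JQ1-PA on JQ1 changes was 0.969, at 0.951 for genes that rose and 0.987 for genes that fell. A response score, the mean signed log2 change over the 10732 genes, was 0.555 ± 0.0018 in JQ1 and 0.534 ± 0.00339 in JQ1-PA (SD, n = 3), 96.3% of the JQ1 value (difference -0.0208, exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 allow). On the lists reported to rise or fall under BET inhibitors alone the difference was -0.111 (exact two-sided permutation p = 0.1).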

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

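The test of JQ1-PA as a weaker dose of JQ1 on the genes higher in JQ1-PA was chosen only after the result was seen, as was the removal of 2 unnamed gene models. Each gene here was singled out because the effects of JQ1-PA and JQ1 against DMSO differed in limma (Benjamini-Hochberg adjusted p under 0.05); the values are log2 differences, JQ1-PA minus JQ1.

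OSGIN1 (1.26), NQO1 (1.04), GCLM (0.79), HMOX1 (0.74) and SLC48A1 (0.64) were higher in JQ1-PA. If JQ1 replicate 3 stands apart and made the difference, the calls should have been lost without it. However, 5 of the 5 stayed past the threshold. Under scaling by library size, tested by rescaling with the median of ratios, 5 stayed as well. These genes were chosen as the largest differences with no overlap of libraries, which favours both outcomes. Rescaling moved the median difference over all tested genes only from 0.038 to 0.001. If JQ1-PA acts as a weaker dose of JQ1, genes raised by JQ1 should not pass its level. On a held-out list of NRF2 targets, JQ1 raised 10 genes. Of these, 7 were called higher still in JQ1-PA and 0 lower. The numbers were 7 of 11 after median of ratios scaling and 6 of 10 without JQ1 replicate 3. In the whole list 13 of 22 tested genes were called higher in JQ1-PA than in JQ1 and 0 lower. The counts among raised genes are part of that result and not independent of it. However, 6 of the 11 genes that JQ1 lowered were higher too, as a weaker dose would give. Over all tested genes, 60 of the 4788 that JQ1 raised were called higher still and 41 lower. Of the 5716 it lowered, 237 were called higher and 0 lower. After median of ratios scaling these were 35 and 134 of 5317, and 111 and 28 of 5363. In CPM as deposited more raised genes were called higher still than lower, beside a median difference of 0.038 that favours higher calls. After median of ratios scaling more calls ran back toward DMSO than away, as a weaker dose would give. However, the JQ1 libraries enter both the sorting and the difference with opposite sign, so their noise alone pushes calls toward DMSO. These counts, and the 6 lowered genes of the held-out list, therefore cannot decide on a weaker dose. The result on raised genes covers the held-out list alone. An NRF2-linked response that is larger with JQ1-PA may be a candidate explanation, as a hypothesis: on 22 tested genes of that list camera gave an upward p = 1.44e-17, and p = 0.00755 with an estimated correlation. Impurities, exposure time and batches of compound were not tested.

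The histone genes were lower in JQ1-PA, among them H2AC6 (-0.29), H2BC12 (-0.21), H2AC20 (-0.41), H2BC18 (-0.42), H3C4 (-0.45) and H3C15 (-0.56). If JQ1 replicate 3 stands apart and made the pattern, the list median should move to 0 without it, but it was -0.235 (camera p = 6.07e-11, and p = 0.00255 with an estimated correlation; 3 members called), beside -0.213 with it. If JQ1-PA acts as a weaker dose of JQ1, other genes that rose at least 2-fold with JQ1 should be as much lower. Without JQ1 replicate 3 the histone median lay at percentile 0 of 1000 random lists from 471 such genes, whose median was -0.0582. The random lists were not matched for the size of the rise, a median of 1.95 for the histones in JQ1. A proportionally weaker dose lowers larger rises more, and histone copies share reads, so this does not exclude a weaker dose. Without the variance trend and robust moderation all 6 calls were lost (0.169, 0.109, 0.0809, 0.152, 0.22 and 0.194 in the order above), H3C4 was also lost with a pseudocount of 0.25 (0.0769), and 5 of the 6 rested on single libraries: H2BC12 lost its call without JQ1 replicate 1 (0.052) or JQ1-PA replicate 3 (0.0676), H2AC20 without the same libraries (0.0636 and 0.145). H3C4 lost it without JQ1 replicate 1 (0.189), JQ1 replicate 2 (0.0734), JQ1-PA replicate 2 (0.0585) or JQ1-PA replicate 3 (0.345), H2BC18 without JQ1 replicate 3 (0.15), JQ1-PA replicate 2 (0.138) or JQ1-PA replicate 3 (0.0967), and H3C15 without JQ1 replicate 3 (0.119) or JQ1-PA replicate 2 (0.212). Reads shared among histone copies, and transcripts that gain a poly(A) tail, were not tested and stay open.

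Most differences between the compounds were higher in JQ1-PA in CPM as deposited (88.6%). The share hung in part on JQ1 replicate 3: it was 66.6% without that library and 86.3% to 93.5% without any other single library. Whether the library composition of JQ1 replicate 3 made the majority stays open, since 66.6% lies between the bounds set in advance for and against. Rescaling by the median of ratios was to decide it too, and by the rule as written its share of 48.4% favoured the composition. It centres the differences, which pulls the share to the middle under any cause, so it was set aside. With the 2 unnamed gene models removed the share was 67.3%.

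The other differences are given as values. GABARAPL1 differed by 0.49, CD180 by 0.28, UTP20 by 0.21 and CDK6 by 0.16, and no single library left out ended these calls, but all 4 were lost without the variance trend and robust moderation (0.118, 0.0546, 0.0937 and 0.255), and UTP20 (0.0754) and CDK6 (0.0601) also with DESeq2. CSF1R differed by 0.30 and lost its call without DMSO replicate 3 (0.0563), JQ1 replicate 1 (0.083), JQ1 replicate 3 (0.099) or JQ1-PA replicate 2 (0.244). It also lost it with a pseudocount of 4 (0.0768), after median of ratios scaling (0.0699), after quantile normalization (0.0811), with only the 2 groups compared (0.119), without the variance trend and robust moderation (0.15), with the 2 gene models removed (0.0515) and with edgeR (0.122). SPI1 differed by 0.18 and lost it without JQ1 replicate 2 (0.107) or JQ1-PA replicate 3 (0.0652), without the variance trend and robust moderation (0.221), with edgeR (0.0564) and with DESeq2 (0.163). SENP6 differed by 0.16 and kept its call in no fit without a single library except that without JQ1 replicate 2 (0.0568 to 0.152 in the others), and lost it in 17 of 21 settings in all, up to 0.366 with DESeq2. HEXIM1 differed by -0.17 and lost it without JQ1 replicate 2 (0.057) or JQ1-PA replicate 3 (0.0576), or without the variance trend and robust moderation (0.208). SAT1 differed by -0.16 and lost it without JQ1 replicate 1 (0.128), JQ1 replicate 2 (0.204), JQ1-PA replicate 2 (0.129) or JQ1-PA replicate 3 (0.178), or without the variance trend and robust moderation (0.357). HNRNPA1P25 differed by -0.47 and lost it without JQ1 replicate 2 (0.131), JQ1 replicate 3 (0.0951) or JQ1-PA replicate 1, 2 or 3 (0.0971, 0.0637 and 0.126), without the variance trend and robust moderation (0.0626) or with a pseudocount of 4 (0.0507).

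Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For JQ1 against DMSO the real split called 10504 genes and the highest other 0, for JQ1-PA against DMSO 10382 and 0, and for JQ1-PA against JQ1 367 and 2. In each, 1 split called as many. Every other split mixes libraries of both groups, so real differences enter the spread and lower the number of gene calls. For gene lists the real split called 11 and the highest other 10 for JQ1 (1 split as many), 10 and 10 for JQ1-PA (3 splits as many) and 6 and 7 between the compounds (2 splits as many).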

How the results depend on the processing

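Removal of the 2 unnamed gene models, and the test of JQ1-PA as a weaker dose of JQ1 on the genes higher in JQ1-PA, were chosen after the data were seen. Calls of the reported genes against DMSO were steady. Most of these genes were chosen for large changes, which favours steady calls. Of their differences under all alternatives, 2088 for JQ1 and 2108 for JQ1-PA kept direction and side of the threshold. The call was lost in 7 and 1 and gained in 0 and 7, and 2 and 2 turned. Between the compounds 452 stayed, 74 lost the call and 4 turned. Of list results 429 stayed for JQ1, 436 for JQ1-PA and 376 between the compounds, where 12 lost the call, 14 gained it and 35 turned. DESeq2 gave no adjusted p for 10 of 227 named-gene differences. Leaving out each library gave 4416 to 4943 genes higher and 5349 to 5727 lower for JQ1, and 4871 to 5279 higher and 4994 to 5293 lower for JQ1-PA. Where results turned, the cause was not tested. Depth limits low genes, where a count of 0 allows up to 0.167 CPM.

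Between JQ1-PA and JQ1, higher and lower calls numbered 325 and 42. They were 163 and 174 after median of ratios scaling, 197 and 139 after quantile normalization, 38 and 3 without the variance trend and robust moderation, 181 and 240 with edgeR, and 70 and 100 with DESeq2. With the 2 gene models removed, 120 were lower. Leaving out 1 library gave 130 (JQ1-PA replicate 3) to 315 (JQ1 replicate 1) higher, 12 (JQ1-PA replicate 3) to 123 (JQ1 replicate 3) lower and 3 (JQ1-PA replicate 3) to 8 (JQ1 replicate 1) called lists. JQ1-PA replicate 2 left 173 and 18, and lower calls were 22 without JQ1 replicate 1 and 26 without JQ1 replicate 2. The covariance of the fold changes (0.349) was 0.451 and 0.221 with pseudocounts of 0.25 and 4, 0.34 with no filter, 0.372 at a mean CPM of at least 5, 0.347 after quantile normalization and 0.349 to 0.352 without single libraries.

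Against DMSO, quantile normalization turned the mitochondrial list (-0.0832 for JQ1, 0 for JQ1-PA), MT-CO1 (-0.209 and 0) and MT-CO3 (-0.343 and -0.297), and the interferon list for JQ1 turned at a mean CPM of at least 5 (-0.00243) and ran from -0.00417 (without DMSO replicate 1) to 0.061 without single libraries.

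List medians between the compounds turned as follows. With median of ratios scaling they were -0.000615 for MLL fusion targets, -0.00518 for ribosome biogenesis, -0.0254 for glycolysis, -0.00986 for NF-kB genes, -0.00454 for mitosis, -0.00789 for apoptosis regulators, -0.0376 for lysosome and autophagy, -0.0323 for housekeeping references and -0.0196 for mitochondrial transcripts. After quantile normalization they were -0.000395 for glycolysis, -0.0159 for NF-kB genes, -0.0106 for apoptosis regulators and -0.0281 for lysosome and autophagy. With the 2 gene models removed they were -0.0123 for glycolysis, -0.0234 for lysosome and autophagy, -0.0177 for housekeeping references and -0.00507 for mitochondrial transcripts. The interferon list turned with no filter (0.0158) and at a mean CPM of at least 5 (0.00267), where the lysosome list was -0.000447.

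Without single libraries the medians ran from -0.0546 (JQ1 replicate 3) to 0.00271 (JQ1 replicate 1) for BET proteins and P-TEFb, -0.00226 (JQ1 replicate 3) to 0.0558 (JQ1 replicate 2) for ribosome biogenesis, -0.0299 (JQ1-PA replicate 2) to 0.0184 (JQ1-PA replicate 3) for interferon genes and -0.0406 (JQ1 replicate 3) to 0.0164 (JQ1 replicate 2) for ribosomal proteins. From JQ1 replicate 3 to JQ1 replicate 1 left out they ran from -0.00643 to 0.0327 for glycolysis, -0.000532 to 0.0552 for NF-kB genes, -0.0562 to 0.0253 for stress responses, -0.024 to 0.0375 for lysosome and autophagy and -0.0202 to 0.0258 for housekeeping references. Mitochondrial transcripts ran from -0.00706 (JQ1 replicate 3) to 0.0407 (JQ1-PA replicate 1), BRD2 from -0.0546 (JQ1 replicate 3) to 0.0125 (JQ1 replicate 2) and BRD3 from -0.0548 to 0.0116 with the same libraries left out.

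The replicate numbers do not pair the libraries: of 9 pairs of same-numbered libraries 1 correlated above 0.1 (range -0.079 to 0.12), and 4 of 9 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block limma called 4820 genes higher and 5739 lower for JQ1, 5204 and 5226 for JQ1-PA and 374 and 53 between the compounds, 14736 genes were equivalent within 1.5-fold, and the list of BET proteins and P-TEFb was gained between the compounds (adjusted p = 0.0495).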

Other observations

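The hypothesis on NRF2 targets was tested on a list written after the 5 genes of the report were seen and before the list's own values were; TALDO1 and the genes named here were chosen after their values were seen. Of 29 NRF2 targets outside those 5 genes, 22 were tested. Of these, 13 were higher in JQ1-PA than in JQ1 in limma (Benjamini-Hochberg adjusted), 0 lower and 20 positive (median log2 difference 0.17). MAFG, a small MAF partner of NRF2, stood at 198 ± 8.82 CPM in JQ1 and 250 ± 2.4 CPM in JQ1-PA (n = 3; limma adjusted p = 3.42e-12), PGD, of the pentose phosphate pathway, at 330 ± 8.19 and 403 ± 6.61 CPM (3.48e-10), EPHX1, an epoxide hydrolase, at 48.7 ± 0.543 and 60.2 ± 0.383 CPM (2.02e-05), and the ferritin gene FTH1 at 216 ± 14.2 and 253 ± 7.38 CPM (1.08e-05). GCLC, the catalytic partner of GCLM, stood at 32.1 ± 0.755 and 38.6 ± 0.994 CPM (0.00221). SQSTM1 (125 and 124 CPM), ABCC1 (35.4 in each) and BLVRB did not differ past the threshold. The values would be consistent with a larger NRF2-linked response to JQ1-PA (camera p = 1.44e-17, 1.81e-15 without JQ1 replicate 3 and 5.55e-17 after median of ratios scaling; p = 0.00755 with an estimated correlation of 0.222), a hypothesis found and tested on the same libraries. Against DMSO the list went both ways, with 10 higher and 11 lower in JQ1 (median 0.0181) and 11 higher and 9 lower in JQ1-PA (0.149).

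Markers of other blood cells were low or mixed beside the granulocyte genes. NKG7, a granule protein gene of NK and T cells, fell from 25.3 CPM to 14.9 and 13.3 CPM in JQ1 and JQ1-PA (limma adjusted p = 2.63e-17 and 1.05e-21), while CD3G and KLRD1 did not pass. The erythroid marker EPOR stood at 15.1, 15 and 14.2 CPM and did not pass. Of 2 tested megakaryocyte markers, GP1BA was called in JQ1 (1.32 to 2.12 CPM, limma adjusted p = 0.00178) and not in JQ1-PA (1.70 CPM, 0.109), and ITGA2B in neither. KRT8, the tested epithelial marker, stood at 6.58, 5.49 and 5.54 CPM (0.0343 and 0.0494). Limma called 0 of the tested markers between the compounds.

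The first principal component of the 9 libraries held 88.9% of the variance and parted both compounds from DMSO. The next held 2.83% and placed JQ1 replicate 3 at -15.4, where the other JQ1 libraries lay at -0.7 and 0.7. In that library the 10 most abundant genes took 12.1% of reads, against 6.35 to 8.21% in the others.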
